A study of Homo sapiens with 6 samples.

How the data were processed

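Libraries from 6 samples of HCT116 cells were used, 3 described as negative and 3 as positive for ZsGreen fluorescence. Per the labels' protocols, total RNA was isolated with TRIzol and the miRNeasy Micro kit, and libraries were made with the TruSeq Stranded mRNA kit, which selects RNA with a poly(A) tail and keeps strand. The authors deposited 1 table of FPKM values (fragments per kilobase of transcript per 1000000 mapped fragments) per library, with 1 value for each of 26255 gene symbols. Per the submitters' processing notes the tools were TopHat2 2.1.1, Bowtie2 2.2.8, SAMtools 0.1.18 and Cuffdiff 2.2.1 with the genome build hg19, but the settings of each, the annotation, the scaling between libraries and the treatment of strand are not given in the sources used here. FPKM divides by gene length and by a total, so that a few abundant RNAs can shift all other values, and very short genes can be over- or understated. Small RNA genes took 67.7% ± 0.265 of the summed FPKM in the ZsGreen-negative and 67.3% ± 1.14 in the ZsGreen-positive libraries (SD, n = 3 each; exact permutation test, two-sided, p = 0.8). The 10 most abundant genes took 57.2% ± 0.277 and 46.3% ± 1.02, and ribosomal protein genes 11.2% ± 0.209 and 9.00% ± 0.205 (exact permutation test, two-sided, p = 0.1 for each of these shares, the smallest possible).

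Depth was estimated from the deposited FPKM values. In replicate 1 of each group, the value of a single fragment was taken as the most common low value of FPKM times length within a preset range. It was sought among 2209 genes with 1 annotated transcript of at least 1000 nt. The other libraries were tied to this value by the most common ratio of low genes between libraries. That ratio was sought only near equality, so libraries of a group could not come out with very different depths. The step was checked on genes at 1 fragment in replicate 1, whose ratio to the same gene elsewhere does not depend on gene length. In ZsGreen-positive replicates 2 and 3, 18 of 21 and 13 of 13 such genes lay within 0.05 of a whole number of estimated steps (10% by chance), 9 and 8 of them at odd numbers. These counts include genes at 1 step, which the tie itself favours. Among genes at 2 or more steps, 17 of 20 and 12 of 12 lay at whole numbers. A gene was counted at a whole number of fragments within a tolerance of 0.3 fragments. The estimate gave 9180000 to 9650000 fragments per ZsGreen-negative and 11900000 to 13300000 per ZsGreen-positive library, and it counts fragments after any scaling between libraries by the authors. Lengths and GC content came from a GRCh38 annotation, matched by symbol for 98.0% of the tested genes, and no coordinates of that build were used. Estimated fragments are not the authors' counts, so no count model was run. Over genes with 5 to 400 estimated fragments, pairs of ZsGreen-negative libraries differed by 1.41 to 1.71 times the counting variance and pairs of ZsGreen-positive libraries by 12.8 to 14.2 times. This sets the spread against counting error alone, which holds only for independent fragments. All were kept as separate libraries.

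Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a mean-variance trend, two-sided) on log2(FPKM + 1), over the 12213 genes with a mean FPKM of at least 1 over the 6 libraries, with the Benjamini-Hochberg adjustment and a threshold of 0.05. The model had 4 residual and 3.22 prior degrees of freedom. A log2 fold change on this scale understates the change of low genes. Of genes with a mean of 1 to 2 FPKM 30.1% passed, and of those at 50 FPKM or more 79.0%. Values of 0 can be failed estimates, and for named genes that were tested and are listed at 0 in some library, small RNA genes aside, the values of each library are given. Before the data were examined, 39 gene lists were fixed from general knowledge, covering the proteasome, ubiquitin and polyamines, stem cell, signalling and lineage genes, metabolism, stress, cell cycle and repair, and markers of other cells. The 31 lists with at least 5 tested members were tested with camera (preset inter-gene correlation of 0.01, two-sided, adjusted over the lists), with camera using an estimated correlation, and with fry. Library properties were compared with exact permutation tests in Python 3.11.15 with SciPy 1.17.1, NumPy 2.4.6 and pandas 2.3.3.

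The rule for naming genes was also fixed before the data were examined. It takes the 10 largest rises and 10 largest falls among genes past the threshold whose groups do not overlap, leaving out small RNA genes, then up to 4 passing members of each list with the largest log2 fold change (where none passes, the 2 members with the highest mean, as values), and 14 fixed genes (ODC1, OAZ1, PSMB5, PSMD14, PSMD1, CD44, PROM1, ALCAM, EPCAM, LGR5, ALDH1A1, ABCG2, MYC and AXIN2). Alternatives fixed at the same time were other pseudocounts (0.1, 0.01 and 5), no filter and a filter at 5 FPKM, rescaling to a sum of 1000000, quantile normalisation, median-of-ratios scaling, limma without trend and with a robust prior, a replicate block, each library left out, a threshold of 0.01, and the other list tests. After seeing the data, 5 were added: ZsGreen-positive replicate 1 as the only positive library, rescaling without small RNA genes, removal of a length trend or of a GC trend (loess, span 0.3), and library weights per group.

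The fit was tested on simulated data for the same comparison, with 12213 genes of which 200 were changed. The changed genes were drawn only from those with a ZsGreen-negative mean log2(FPKM + 1) above 1, so recovery of lower genes was not tested. The fit recovered 31 of 67 changes of 0.5 (46.3%), 49 of 67 of 1 (73.1%) and 65 of 66 of 2 log2 units (98.5%). It also called 26 unchanged genes (0.216% of the unchanged genes). Beside the 31, 49 and 65 true calls, these 26 are a larger share of calls than the threshold of 0.05 aims at. The adjusted p thus understated false calls in this simulation. Whether it does so in the real data, where 7258 genes were called, was not tested. A simulated list of 30 genes raised by 1 log2 unit had a camera p of 2.3e-64 and a list of 30 unchanged genes one of 0.10. The simulated genes varied independently, so this does not test whether the preset correlation suits the real lists. Some genes that the rule names are not reported. Sequence of the ZsGreen reporter and alignments were not used here.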

Results

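Messenger RNA was sequenced from HCT116 cells, an established human colorectal carcinoma line, which carried a reporter of the fluorescent protein ZsGreen joined to the degron of ornithine decarboxylase. This degron sends a protein to the proteasome without ubiquitin, so that fluorescence builds up where the reporter is degraded slowly. The labels divide the libraries into 3 from ZsGreen-negative and 3 from ZsGreen-positive cells, and the series title places the cells among models of cancer stem cells. The comparison asks how the transcriptome of cells that kept the fluorescence differs from that of cells that did not. Every mean is given with its SD over n = 3 libraries per group. Every log2 fold change, positive minus negative on the log2(FPKM + 1) scale, is given with its SE. Where a pair of means is given, the ZsGreen-negative mean stands before the ZsGreen-positive one. Nothing in the labels says that the libraries came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

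The estimated depth was 9650000, 9180000 and 9340000 fragments in ZsGreen-negative replicates 1 to 3. It was 11900000, 12400000 and 13300000 fragments in ZsGreen-positive replicates 1 to 3. In each group the tie to replicate 1 allowed only similar depths in replicates 2 and 3. About as many genes reached an FPKM of 1 in both groups, 12015 ± 10.5 against 12036 ± 47.0 (exact permutation test, two-sided, p = 0.5). Genes listed at 0 numbered 8985, 9040 and 9162 in the ZsGreen-negative and 10314, 11624 and 11989 in the ZsGreen-positive libraries (exact permutation test, two-sided, p = 0.1, the smallest that 3 against 3 can give). ZsGreen-positive replicates 2 and 3 stood apart from the rest in their share of genes at 1 fragment. Of single-transcript genes with 1 to 8 estimated fragments, 9.88% and 12.3% were at 1 fragment in these libraries, against 30.2% in ZsGreen-positive replicate 1 and 34.3% to 40.2% in the ZsGreen-negative libraries. In spread, ZsGreen-positive replicate 1 was like the other positive libraries. Its pairs with replicates 2 and 3 differed by 12.84 and 13.85 times the counting variance. Replicates 2 and 3 differed from each other by 14.19 times.

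FPKM of cell cycle genes and replication-dependent histones was far higher in the ZsGreen-positive than in the ZsGreen-negative libraries. FPKM of interferon-stimulated genes, NF-kappaB and NRF2 targets and immediate early genes was lower. Of these lists, the cell cycle and interferon-stimulated ones kept their calls with an estimated correlation. The calls of histones (adjusted p = 0.125), NF-kappaB targets (adjusted p = 0.0668), NRF2 targets (adjusted p = 0.0766) and immediate early genes (adjusted p = 0.241) were lost with an estimated correlation. A batch that coincides with the groups cannot be told apart from them, and more RNA without a poly(A) tail stays open for the histones. RRM2, a subunit of ribonucleotide reductase, rose from 5.07 ± 0.319 to 69.4 ± 7.60 FPKM. CDK1, the mitotic kinase, rose from 8.41 ± 0.349 to 93.3 ± 5.72 FPKM. CXCL8, which encodes the chemokine interleukin-8, fell from 108 ± 6.94 to 2.73 ± 0.409 FPKM. IFI6, an interferon-stimulated gene, fell from 353 ± 11.0 to 21.2 ± 1.33 FPKM. Transcripts of the proteasome were moderately higher in ZsGreen-positive cells, but the calls of the 20S list (adjusted p = 0.211) and the 19S list (adjusted p = 0.0794) were lost with an estimated correlation. ODC1, the source of the degron, was at 291 ± 9.64 against 296 ± 3.16 FPKM.

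Of 12213 genes tested with limma, 7258 (59.4%) passed an adjusted p of 0.05, 3590 of them higher and 3668 lower in ZsGreen-positive cells. At least 2-fold changes were found for 2177 of these genes, 1158 higher and 1019 lower. The values of the groups did not overlap for 67.6% of the tested genes, where chance gives 10%. The balance of directions depended on the scaling. The median log2 fold change of all tested genes was 0.0040 with the deposited values and 0.14 with every library rescaled to a sum of 1000000. Under this rescaling 4281 of 6890 called genes were higher (62.1%, against 49.5% with the deposited values). Of the genes changed at least 2-fold it made 69.2% higher, against 53.2%. The changes below are those in the deposited values, and the called directions of the gene lists held under each rescaling. Under the rescaling to 1000000, however, some list medians moved by over 1.5 times, to -0.27 for stem cell markers, -0.53 for mesenchymal markers, -0.29 for p53 targets, -0.35 for antigen presentation, -0.11 for autophagy and lysosome genes and -0.31 for ribosomal proteins. With no filter they moved as far to -0.28 for stem cell markers, -0.38 for mesenchymal markers, -0.73 for NRF2 targets and -0.90 for TGF-beta targets. With a pseudocount of 5 they moved to 1.51 for G2/M genes, -0.88 for NF-kappaB targets, -0.26 for antigen presentation and -0.35 for mesenchymal markers. Removing the GC trend gave -0.88 for antigen presentation, and rescaling without small RNA genes -0.13 for autophagy and lysosome genes. The leading principal component, with 81.9% of the variance, separated the groups. Pearson correlations across genes, which are not independent replicates, were 0.986 to 0.988 within the ZsGreen-negative group, 0.967 to 0.971 within the ZsGreen-positive group and 0.844 to 0.857 between the groups.

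The 10 largest rises included 6 replication-dependent histone genes, among them HIST1H2BL (4.82 ± 0.989 to 249.9 ± 80.4 FPKM; log2 fold change 5.40 ± 0.22, adjusted p = 2.54e-06), HIST1H2BM (2.54 ± 1.31 to 129.9 ± 30.2 FPKM) and HIST1H2AJ (31.4 ± 5.17 to 647 ± 87.4 FPKM). PLCG2, which encodes the signalling enzyme phospholipase C gamma 2, rose from 35.7 ± 2.61 to 619.6 ± 106 FPKM (log2 fold change 4.07 ± 0.12, adjusted p = 7.25e-07). CDC45, a part of the replicative helicase, rose from 0.799 ± 0.264 to 26.0 ± 5.08 FPKM (log2 fold change 3.90 ± 0.18, adjusted p = 3.86e-06). The remaining rises were MTRNR2L2 (1.47 ± 0.767 to 101 ± 20.3 FPKM) and MTRNR2L9, listed at 0.270, 0 and 0 FPKM in the ZsGreen-negative and 53.2, 49.6 and 29.6 FPKM in the ZsGreen-positive libraries. Both closely resemble the mitochondrial 16S ribosomal RNA gene, and the histone genes resemble one another, so the values of single members are uncertain.

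The largest falls included genes of secreted proteins and interferon-stimulated genes. THBS1, which encodes the matrix protein thrombospondin 1, fell from 60.0 ± 0.263 to 1.36 ± 0.497 FPKM (log2 fold change -4.71 ± 0.15, adjusted p = 1.08e-06). CXCL8 had a log2 fold change of -4.88 ± 0.10 (adjusted p = 1.64e-07) and IFI6 one of -4.00 ± 0.0643 (adjusted p = 3.79e-08). NR4A1, an immediate early nuclear receptor gene, fell from 91.4 ± 6.44 to 5.16 ± 1.77 FPKM. BIRC3, an inhibitor of apoptosis, fell from 35.5 ± 0.861 to 1.65 ± 0.942 FPKM, and LCN2, which encodes lipocalin 2, fell from 24.4 ± 2.60 to 1.70 ± 1.18 FPKM. IFI27 was at 56.8, 42.5 and 47.8 FPKM in the ZsGreen-negative and 5.40, 0.865 and 0 FPKM in the ZsGreen-positive libraries. The pseudogene WFDC21P was at 13.8, 17.3 and 14.4 against 1.00, 0 and 0 FPKM.

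Cell cycle genes rose almost without exception. Of 50 tested genes of the G1/S phase, 49 rose, 0 fell and 1 did not pass. The median of this list was 2.03 (camera adjusted p = 1.82e-21; adjusted p = 0.00429 with an estimated correlation). Adjusted over the list alone, 49 rose. Beside RRM2 and CDC45, GINS2, another helicase part, rose from 4.38 ± 0.0908 to 56.8 ± 3.92 FPKM. E2F1, a transcription factor of S phase entry, rose from 0.356 ± 0.0298 to 13.6 ± 2.75 FPKM (log2 fold change 3.41 ± 0.17, adjusted p = 4.53e-06). Of 54 genes of the G2/M phase, 53 rose, 0 fell and 1 did not pass, and 54 rose adjusted over the list alone. Its median log2 fold change was 2.34 (camera adjusted p = 1.82e-21; adjusted p = 0.00429 with an estimated correlation). AURKB, the mitotic kinase aurora B, rose from 2.45 ± 0.389 to 37.0 ± 5.17 FPKM (log2 fold change 3.46 ± 0.13, adjusted p = 1.84e-06). BIRC5, which encodes survivin, rose from 5.54 ± 0.842 to 62.9 ± 2.68 FPKM, and the mitotic kinesin gene KIF2C from 3.30 ± 0.249 to 41.0 ± 2.44 FPKM.

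Of 42 tested replication-dependent histone genes out of 61, 39 rose, 0 fell and 3 did not pass, both over all genes and adjusted over the list alone. These members had a median of 2.49 (camera adjusted p = 1.58e-18; adjusted p = 0.125 with an estimated correlation). Histone genes took 0.354% ± 0.0137 of the summed FPKM in the ZsGreen-negative and 1.55% ± 0.0040 in the ZsGreen-positive libraries (exact permutation test, two-sided, p = 0.1). Among 35 DNA repair genes, 29 rose, 2 fell and 4 did not pass, with the same counts adjusted over the list alone. As a list they had a median log2 fold change of 1.10 (camera adjusted p = 1.87e-08; adjusted p = 0.0248 with an estimated correlation). The rises were led by genes of the Fanconi anaemia pathway, with FANCI going from 4.23 ± 0.169 to 31.5 ± 2.95 FPKM, FANCD2 from 2.52 ± 0.279 to 18.5 ± 0.855 FPKM and FANCA from 2.36 ± 0.123 to 17.4 ± 3.40 FPKM. LIG1, a DNA ligase, rose from 4.82 ± 0.737 to 25.8 ± 3.19 FPKM. With ZsGreen-positive replicate 1 as the only positive library, 49 G1/S genes, 53 G2/M genes, 41 histone genes and 31 DNA repair genes rose.

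With the main settings, interferon-stimulated genes had the lowest median of the 31 lists. At a minimum mean FPKM of 5, TGF-beta targets were lower (-2.30 against -2.05). Of 29 tested interferon-stimulated genes, 27 fell, 0 rose and 2 did not pass, the same adjusted over the list alone. Here the median log2 fold change was -2.01 (camera adjusted p = 1.12e-10; adjusted p = 0.0493 with an estimated correlation). OAS1, an antiviral sensor of double-stranded RNA, fell from 20.3 ± 1.48 to 1.63 ± 1.12 FPKM (log2 fold change -3.13 ± 0.33, adjusted p = 0.000162). IFITM1, a membrane protein that restricts virus entry, fell from 67.4 ± 4.05 to 6.97 ± 1.76 FPKM (log2 fold change -3.13 ± 0.16, adjusted p = 5.79e-06). Of 13 genes of antigen presentation by MHC class I, 9 fell, 1 rose and 3 did not pass, also adjusted over the list alone. For the list, the median was -0.54 (camera adjusted p = 0.0212; adjusted p = 0.451 with an estimated correlation). B2M, the invariant light chain, fell from 1139 ± 63.0 to 456 ± 19.7 FPKM. The member that rose was CALR, a chaperone of the endoplasmic reticulum (160.3 ± 3.64 to 396 ± 25.7 FPKM). Without ZsGreen-positive replicate 2 this list had a camera adjusted p of 0.0526, and it passed under 20 of 24 alternatives (adjusted p 0.0013 to 0.451).

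Targets of 3 signalling pathways and immediate early genes were lower as well. Of 14 tested NF-kappaB targets, 11 fell, 0 rose and 3 did not pass, both over all genes and adjusted over the list alone. The median of this list was -1.49 (camera adjusted p = 0.000272; adjusted p = 0.0668 with an estimated correlation). CXCL8, BIRC3 and LCN2 were among the members that fell. Of 14 TGF-beta targets, 10 fell, 0 rose and 4 did not pass, the same adjusted over the list alone. Its median log2 fold change was -1.62 (camera adjusted p = 0.00110; adjusted p = 0.167 with an estimated correlation). CDKN2B, which encodes the kinase inhibitor p15, fell from 17.3 ± 0.712 to 2.02 ± 0.704 FPKM (log2 fold change -2.63 ± 0.18, adjusted p = 1.84e-05). CTGF, a secreted matrix-associated protein, fell from 10.6 ± 0.225 to 0.992 ± 0.506 FPKM (log2 fold change -2.58 ± 0.20, adjusted p = 3.9e-05). YAP/TAZ targets, which share CTGF with that list, gave 16 lower, 0 higher and 2 not passing of 18, the same adjusted over the list alone. These members had a median of -0.91 (camera adjusted p = 1.96e-05; adjusted p = 0.0591 with an estimated correlation). IGFBP3 of this list fell from 20.5 ± 0.589 to 3.40 ± 1.10 FPKM and NT5E, the ectonucleotidase CD73, from 17.3 ± 0.509 to 3.99 ± 1.22 FPKM. Immediate early and dissociation stress genes gave 21 lower, 0 higher and 3 not passing of 24, and 22 lower adjusted over the list alone. As a list they had a median log2 fold change of -1.14 (camera adjusted p = 1.57e-06; adjusted p = 0.241 with an estimated correlation). With ZsGreen-positive replicate 1 as the only positive library the median was -0.72. DUSP5, a phosphatase of MAP kinases, fell from 327 ± 6.97 to 48.6 ± 4.01 FPKM (log2 fold change -2.73 ± 0.0709, adjusted p = 4.3e-07).

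Genes of the oxidative stress response were lower in ZsGreen-positive cells. Of 23 tested NRF2 targets, 19 fell, 3 rose and 1 did not pass, unchanged adjusted over the list alone. Here the median log2 fold change was -1.29 (camera adjusted p = 2.26e-06; adjusted p = 0.0766 with an estimated correlation). HMOX1, haem oxygenase 1, fell from 66.2 ± 4.77 to 9.71 ± 2.54 FPKM. GCLC and GCLM encode the subunits of the rate-limiting enzyme of glutathione synthesis. GCLC fell from 148 ± 1.93 to 23.4 ± 2.12 FPKM (log2 fold change -2.61 ± 0.0742, adjusted p = 5.88e-07). GCLM fell from 23.7 ± 1.07 to 3.19 ± 0.0730 FPKM (log2 fold change -2.56 ± 0.0832, adjusted p = 1.08e-06). Of 28 autophagy and lysosome genes, 15 fell, 4 rose and 9 did not pass, the same adjusted over the list alone. For the list, the median was -0.29 (camera adjusted p = 0.0212; adjusted p = 0.148 with an estimated correlation). With ZsGreen-positive replicate 1 as the only positive library the camera adjusted p was 0.0793, and the list passed under 20 of 24 alternatives (adjusted p 4.47e-05 to 0.148). The autophagy receptor gene SQSTM1 fell from 654 ± 7.79 to 115 ± 4.67 FPKM (log2 fold change -2.50 ± 0.0533, adjusted p = 1.68e-07). MAP1LC3B, a protein of the autophagosome membrane, fell from 103 ± 2.87 to 15.2 ± 1.71 FPKM.

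Of 24 HIF targets, 19 fell, 1 rose and 4 did not pass, and 20 fell and 2 rose adjusted over the list alone. The median of this list was -0.92 (camera adjusted p = 7.45e-06; adjusted p = 0.0766 with an estimated correlation). ADM, which encodes adrenomedullin, fell from 266 ± 9.59 to 41.2 ± 7.22 FPKM (log2 fold change -2.67 ± 0.11, adjusted p = 2.94e-06). The histone demethylase gene KDM3A fell from 27.9 ± 0.957 to 8.18 ± 0.444 FPKM. Of 25 genes of cholesterol biosynthesis, 20 fell, 1 rose and 4 did not pass, with 20 lower and 2 higher adjusted over the list alone. Its median log2 fold change was -0.66 (camera adjusted p = 3.18e-06; adjusted p = 0.0429 with an estimated correlation). INSIG1, a sterol-regulated protein, fell from 241 ± 6.20 to 51.0 ± 2.56 FPKM and MSMO1, a sterol oxidase, from 318 ± 3.32 to 73.5 ± 3.97 FPKM. Among 27 p53 targets, 14 fell, 4 rose and 9 did not pass, as they did adjusted over the list alone. These members had a median of -0.47 (camera adjusted p = 0.00458; adjusted p = 0.0794 with an estimated correlation). TNFRSF10B, a death receptor, fell from 192 ± 2.80 to 58.9 ± 3.37 FPKM. FDXR, a mitochondrial reductase, rose from 14.5 ± 0.431 to 56.7 ± 6.33 FPKM.

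Nuclear genes for subunits of oxidative phosphorylation rose and cytosolic ribosomal protein genes fell. Of 76 such subunit genes, 59 rose, 2 fell and 15 did not pass, also adjusted over the list alone. As a list they had a median log2 fold change of 0.57 (camera adjusted p = 1.12e-10; adjusted p = 0.310 with an estimated correlation). After quantile normalisation this median was 0.34, with 48 genes higher and 8 lower. NDUFV1 of complex I rose from 32.8 ± 1.17 to 106 ± 4.79 FPKM (log2 fold change 1.66 ± 0.0621, adjusted p = 1.78e-06). ATP5G1 of the ATP synthase rose from 53 ± 2.41 to 178 ± 46.7 FPKM. Of 78 ribosomal protein genes, 59 fell, 5 rose and 14 did not pass, with 61 lower adjusted over the list alone. Here the median log2 fold change was -0.49 (camera adjusted p = 1.91e-07; adjusted p = 0.529 with an estimated correlation). With ZsGreen-positive replicate 1 as the only positive library this median was -0.31, with 55 lower and 12 higher. RPS16 fell from 1277 ± 32.5 to 458 ± 51.9 FPKM and RPL26 from 5783 ± 232 to 2945 ± 373 FPKM. Of 17 glycolysis enzymes, 9 rose, 5 fell and 3 did not pass, the same adjusted over the list alone, and the list did not pass as a whole (camera adjusted p = 0.235; higher with fry, adjusted p = 0.0039). PFKL, a phosphofructokinase gene, rose from 10.9 ± 0.633 to 64.7 ± 5.30 FPKM (log2 fold change 2.47 ± 0.0846, adjusted p = 1.35e-06). ALDOC, an aldolase gene, fell from 169 ± 2.12 to 71.2 ± 11.5 FPKM.

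Because the reporter is read out by the proteasome, genes of that complex were set beside those for ubiquitin and polyamines. Of 14 genes of the 20S core, 11 rose, 0 fell and 3 did not pass. For the list, the median was 0.51 (camera adjusted p = 0.000272; adjusted p = 0.211 with an estimated correlation). Of 22 genes of the 19S regulatory particle, 15 rose, 0 fell and 7 did not pass. The median of this list was 0.43 (camera adjusted p = 0.000686; adjusted p = 0.0794 with an estimated correlation). Both lists gave these counts adjusted over the list alone. After quantile normalisation the 20S median was 0.23, with 9 genes higher and 2 lower. The largest rises were those of PSMB3 (124 ± 3.46 to 273 ± 17.1 FPKM; log2 fold change 1.13 ± 0.0633, adjusted p = 8.56e-06) and PSMD2 (46.1 ± 1.42 to 104 ± 2.79 FPKM; log2 fold change 1.16 ± 0.0560, adjusted p = 4.47e-06). PSMB5, which carries the chymotrypsin-like activity, rose from 153 ± 5.56 to 208 ± 13.2 FPKM (log2 fold change 0.44 ± 0.0649, adjusted p = 0.00085). PSMD14, the deubiquitinase of the lid, had 105 ± 1.38 against 120.5 ± 8.80 FPKM (log2 fold change 0.19 ± 0.0669, adjusted p = 0.0397). PSMD1, a scaffold of the base, had 52.4 ± 1.59 against 70.9 ± 12.5 FPKM (log2 fold change 0.42 ± 0.12, adjusted p = 0.0212). PSMD14 passed under 14 and PSMD1 under 18 of 23 alternatives. PSMD14 lost its call without any 1 of 5 libraries, all but ZsGreen-positive replicate 2 (adjusted p 0.0746 to 0.123). PSMD1 lost it without any 1 ZsGreen-negative library or ZsGreen-positive replicate 1 (adjusted p 0.0511 to 0.0695).

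Of 7 genes of the immunoproteasome and proteasome activators, 3 fell, 2 rose and 2 did not pass, the same adjusted over the list alone (camera adjusted p = 0.501; lower with fry, adjusted p = 0.0192). PSMB9, the interferon-inducible beta subunit, fell from 15.2 ± 1.32 to 6.10 ± 0.925 FPKM and PSME4, an activator, from 24.5 ± 0.612 to 9.65 ± 1.94 FPKM. The 28 ubiquitin and conjugation genes went both ways, 11 higher, 8 lower and 9 not passing over all genes and adjusted over the list alone (camera adjusted p = 0.845). Their median log2 fold change was 0.03 and their mean -0.03, and limma's fry, which asks if members move one way on balance, gave a downward direction (adjusted p = 0.0336, the 1 of 24 alternatives that passed). PSMG1, a proteasome assembly chaperone, rose from 27.6 ± 0.268 to 56.0 ± 4.58 FPKM and USP14, a proteasome-bound deubiquitinase, fell from 9.12 ± 0.602 to 4.04 ± 0.637 FPKM. Polyamine genes gave 5 higher, 6 lower and 8 not passing of 19, and 7 higher and 6 lower adjusted over the list alone. Their median was 0.21, their mean -0.05 and the direction of camera down (adjusted p = 0.988). That direction turned up under 4 of 24 alternatives, and the list passed as lower with fry (adjusted p = 0.0062), while 10 genes were higher with ZsGreen-positive replicate 1 as the only positive library. ARG2, the mitochondrial arginase gene, fell from 59.0 ± 1.81 to 9.67 ± 0.454 FPKM. EIF5A, the translation factor modified with spermidine, rose from 86.1 ± 1.43 to 275 ± 30.3 FPKM. ODC1 did not pass (log2 fold change 0.02 ± 0.0513, adjusted p = 0.704). It was lower after quantile normalisation (log2 fold change -0.36, adjusted p = 0.0010) and higher after rescaling without small RNA genes (0.18, adjusted p = 0.0291, with a median of all genes of 0.15 there), and 21 other alternatives did not pass (adjusted p up to 0.973). OAZ1, the antizyme gene that directs ornithine decarboxylase to the proteasome, had 476 ± 3.94 against 576 ± 79.4 FPKM (log2 fold change 0.27 ± 0.10, adjusted p = 0.0530) and passed under 6 of 23 alternatives (adjusted p 0.0004 to 0.897), among them without ZsGreen-positive replicate 2 (adjusted p = 0.0016).

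Among markers used for colorectal cancer stem cells, more fell than rose. Of 18 tested out of 24, 9 fell, 4 rose and 5 did not pass, the same adjusted over the list alone. Its median log2 fold change was -0.45 (camera adjusted p = 0.0291; adjusted p = 0.147 with an estimated correlation). The list also lost its call with no filter on low values (adjusted p = 0.0548) and with a minimum mean FPKM of 5 (adjusted p = 0.0904), and it passed under 20 of 24 alternatives (adjusted p 3.05e-05 to 0.147). The adhesion receptor CD44 fell from 140.1 ± 2.52 to 65.2 ± 4.05 FPKM (log2 fold change -1.09 ± 0.0624, adjusted p = 9.12e-06). PROM1, which encodes CD133, fell from 22.8 ± 0.791 to 12.9 ± 0.231 FPKM (log2 fold change -0.77 ± 0.0692, adjusted p = 7.22e-05). ALCAM, which encodes CD166, fell from 108 ± 2.17 to 42.7 ± 4.61 FPKM (log2 fold change -1.33 ± 0.0848, adjusted p = 1.49e-05). The complement regulator gene CD55 fell from 53.6 ± 1.17 to 10.5 ± 1.90 FPKM and the transcription factor gene SOX9 from 20.9 ± 0.915 to 6.57 ± 0.915 FPKM. EPCAM had 129 ± 3.86 against 147 ± 7.75 FPKM (log2 fold change 0.18 ± 0.0605, adjusted p = 0.0321). It lost its call without any 1 library other than ZsGreen-positive replicate 3 (adjusted p 0.0526 to 0.128), and its sign turned after quantile normalisation (log2 fold change -0.07, adjusted p = 0.357). ABCG2 did not pass (1.18 ± 0.176 against 0.875 ± 0.493 FPKM; log2 fold change -0.25 ± 0.23, adjusted p = 0.388). LGR5 and ALDH1A1 were below the minimum for testing, with at most 0.0706 and 0.0448 FPKM in any library. Of the pluripotency factors only KLF4, KLF5 and MYC were tested, and all 3 fell (KLF4 from 39.4 ± 1.19 to 8.60 ± 2.71 FPKM, MYC from 167 ± 8.57 to 100.2 ± 17.3 FPKM).

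Of 12 WNT/beta-catenin targets, 6 fell, 2 rose and 4 did not pass, the same adjusted over the list alone. These members had a median of -0.30 (camera adjusted p = 0.124). The list passed as lower under 2 of 24 alternatives, with the GC trend of each library removed (adjusted p = 0.0166) and with fry (adjusted p = 0.0003), and the adjusted p reached 0.245. AXIN2, a negative regulator of the pathway, fell from 10.1 ± 0.303 to 5.68 ± 0.805 FPKM (log2 fold change -0.73 ± 0.11, adjusted p = 0.00105). The growth factor gene BMP4 rose from 33.4 ± 0.832 to 94.5 ± 2.1 FPKM (log2 fold change 1.47 ± 0.0555, adjusted p = 1.78e-06). Of 9 Notch targets, 4 fell, 2 rose and 3 did not pass, the same adjusted over the list alone (camera adjusted p = 0.461; lower with fry, adjusted p = 0.0039). The repressor gene HES1 fell from 78.0 ± 2.45 to 11.4 ± 2.27 FPKM and the ligand gene JAG2 rose from 4.02 ± 0.411 to 9.91 ± 1.31 FPKM. Epithelial markers gave 18 lower, 1 higher and 6 not passing of 25, the same adjusted over the list alone. As a list they had a median log2 fold change of -0.66 (camera adjusted p = 8.15e-05; adjusted p = 0.0922 with an estimated correlation). The tight junction gene CLDN4 fell from 381 ± 5.74 to 93.0 ± 14.2 FPKM and CDH1, which encodes E-cadherin, from 49.8 ± 0.455 to 17.4 ± 1.42 FPKM. Mesenchymal markers gave 6 lower, 0 higher and 3 not passing of 9 tested out of 21, the same adjusted over the list alone. Here the median log2 fold change was -0.80 (camera adjusted p = 0.0232; adjusted p = 0.390 with an estimated correlation). Without ZsGreen-positive replicate 1 the mesenchymal median was -0.49, with 1 higher and 5 lower. The kinase receptor gene AXL fell from 13.9 ± 1.01 to 7.51 ± 0.875 FPKM.

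Protein folding genes and drug transporters went both ways and did not pass as lists with camera. Of 26 genes of the unfolded protein response and ATF4 targets, 9 rose, 12 fell and 5 did not pass (camera adjusted p = 0.324; lower with fry, adjusted p = 0.0010). DDIT3, which encodes CHOP, rose from 39.7 ± 0.937 to 162 ± 35.4 FPKM and the stress factor gene ATF3 fell from 62.0 ± 4.68 to 17.1 ± 1.39 FPKM. Of 19 heat shock protein genes, 7 rose, 7 fell and 5 did not pass (median -0.18, mean -0.10, direction of camera up, adjusted p = 0.988, and down under 11 of 24 alternatives). HSP90AB1 rose from 408 ± 8.25 to 1067 ± 48.9 FPKM and HSPA1B fell from 114 ± 3.27 to 29 ± 2.67 FPKM. Of 14 ABC transporter genes, 5 rose, 2 fell and 7 did not pass (median 0.19, mean -0.0022, direction of camera up, adjusted p = 0.556). ABCC3 fell from 21.7 ± 0.602 to 5.51 ± 1.26 FPKM. All 3 lists gave these counts adjusted over the list alone, and 4 transporter genes were lower with ZsGreen-positive replicate 1 as the only positive library.

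Most markers of other lineages and cell types were below the minimum for testing, though the fibroblast marker S100A4 was abundant. Of enterocyte markers 4 were tested, and 1 rose, the homeobox gene CDX2 (4.47 ± 0.355 to 6.99 ± 1.15 FPKM), which lost its call with the GC trend removed (adjusted p = 0.0988). Of secretory lineage markers 3 were tested with limma and 0 passed, as 0 did at an unadjusted p under 0.05. SYP had 1.56 ± 0.139 against 1.15 ± 0.404 FPKM, with an adjusted p of 0.0456 once the GC trend was removed and up to 0.562 over the alternatives, and KLK10 had 2.25 ± 0.191 against 2.03 ± 0.211 FPKM. Fibroblast markers had 3 tested members, of which S100A4 (1828 ± 40.9 to 1103 ± 116 FPKM) and COL1A1 (2.1 ± 0.113 to 0.865 ± 0.266 FPKM) fell. Leukocyte markers also had 3 tested members, of which CORO1A rose from 0.154 ± 0.163 to 2.56 ± 1.78 FPKM. LYZ was at 2.03, 1.62 and 1.80 FPKM in the ZsGreen-negative and 0.284, 1.53 and 0 FPKM in the ZsGreen-positive libraries (adjusted p = 0.0484). LYZ lost its call without any 1 library other than ZsGreen-positive replicate 2 (adjusted p 0.0966 to 0.131). No endothelial marker reached the minimum for testing, the highest being ENG with 0.367 FPKM in 1 library. Of embryonic kidney markers, included because a kidney line often packages viral vectors, 2 were tested, and CD24 rose from 5.06 ± 0.586 to 10.5 ± 1.03 FPKM. Mitochondrially encoded genes were not analysed here.

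In all, 22 of the 31 lists passed with the preset correlation, 7 higher and 15 lower. With an estimated one 5 passed, namely the G1/S, G2/M and DNA repair lists higher and the interferon-stimulated and cholesterol lists lower. No label gives a batch that holds both groups, so a batch of culture, sorting or library preparation cannot be told apart from the group.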

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

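The alternatives without positive replicates 2 and 3, with small RNA genes left out of the sum, with trends removed and with library weights were chosen after seeing the data, and the others before. For 145 results on named genes, 3274 of 3323 alternative values kept their side of the threshold, 39 fell below it, 8 passed it and 2 reversed a direction with a call on either side. For the 31 lists, 709 of 744 values did so, 27 fell below, 7 passed (6 of them with fry) and 1 reversed. Among the values that kept their side, 4 of genes (ODC1, OAZ1 and KLK10) and 16 of lists (heat shock, polyamine and ubiquitin) changed sign without passing under either setting. The reversals were ODC1 (log2 fold change -0.36, adjusted p = 0.0010) and EPCAM (-0.069, adjusted p = 0.357) under quantile normalisation, and the ubiquitin list under fry (median 0.031, adjusted p = 0.0336), and the cause was not tested. With a pseudocount of 5 the genes changed at least 2-fold numbered 1084, 606 higher and 478 lower, since a larger pseudocount shrinks the change of low genes. Rescaling to a sum of 1000000 gave 598 lower genes changed at least 2-fold, with a median over all tested genes of 0.14. With an estimated correlation 5 lists passed, 3 higher and 2 lower. Leaving out each library in turn gave 5964 to 7579 genes past the threshold (2976 to 3774 higher, 2988 to 3805 lower), 2152 to 2319 changed at least 2-fold (1152 to 1265 higher, 1000 to 1054 lower) and 21 to 22 lists (7 higher, 14 to 15 lower). With ZsGreen-positive replicate 1 as the only positive library 8817 genes passed, the lone library being assumed to vary like the negative group. With no filter 7736 of 18934 genes passed. The replicate block gave 6915 genes (3433 higher, 3482 lower), with PSMD14 and EPCAM losing their calls (adjusted p 0.0752 and 0.0583). The deviations of libraries with the same number correlated at -0.02, -0.03 and -0.02, and no library correlated best with its own number. Summing values of repeated symbols was not run, as no symbol was listed more than once. Depth leaves low genes with few fragments, and fewer of them passed, but whether depth or the pseudocount is the cause was not tested.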

Other observations

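Families of genes that share the start of their symbol were tested after the fixed lists, so these tests were chosen after results were seen. Subunits of the mitochondrial ribosome were higher in ZsGreen-positive cells, 32 of 49 MRPL genes rising and 0 falling (median log2 fold change 0.44, camera adjusted p = 0.0002) and 17 of 30 MRPS genes rising with 1 falling (0.41, adjusted p = 0.0030). Rises also prevailed among MCM genes, mostly of the replicative helicase (8 of 11 higher, 0 lower, median 2.23, adjusted p = 0.0010), nucleoporins (NUP, 16 of 21 higher and 3 lower, 0.70, adjusted p = 0.0084), the RNA exosome (EXOSC, 9 of 10 higher and 0 lower, 0.67, adjusted p = 0.0119), the CCT chaperonin family (7 of 10 higher and 0 lower, 0.57, adjusted p = 0.0135) and the augmin complex of the spindle (HAUS, 7 of 8 higher and 0 lower, 1.09, adjusted p = 0.0162). KLF transcription factors fell (8 of 12 lower and 0 higher, -0.68, adjusted p = 0.0119), as did DNAJB co-chaperones (6 of 8 lower and 0 higher, -0.55, adjusted p = 0.0468). In all 17 families passed with the preset correlation and 0 with an estimated one, where the lowest adjusted p was 0.596. TUBA1B, an alpha-tubulin gene chosen after its values were seen, rose from 72.0 ± 2.23 to 603 ± 50.1 FPKM (log2 fold change 3.05 ± 0.0727, adjusted p = 3.12e-07), and it shares sequence with other tubulin genes.

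The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. The real split was the 1 with the largest counts each time, with 7258 genes (highest other split 1), 2177 genes changed at least 2-fold (highest other 1), 22 lists (highest other 18) and 17 families (highest other 12). Splits that mix the groups gave 12 to 18 lists with the preset correlation, but each of them sets 2 libraries of a group against 1, so part of the difference between the groups remains in it.

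Of the tests that follow, those of batch, of RNA without a poly(A) tail, of fragment number and of distinct molecules were chosen after the results were seen. The fit with the length trend removed was also added after seeing the data. Cell cycle and histone genes, 146 in all, had a median log2 fold change of 2.32 (quartiles 1.42 and 2.92). A length trend between the groups would have taken this away, but the median was 2.28 with the trend of each library removed. With ZsGreen-positive replicate 1 as the only positive library the median was 2.30. That argues against a peculiarity confined to ZsGreen-positive replicates 2 and 3 as the whole cause. A fault that replicate 1 shares, such as few distinct molecules, cannot be decided this way. Its pairs with replicates 2 and 3 differed by 12.84 and 13.85 times the counting variance. Replicates 2 and 3 differed from each other by 14.19 times. Histone mRNA has no poly(A) tail, so more such RNA in the positive libraries was tested on the 16 tested small RNA genes of 200 nt or more, which had a median of -1.11 (quartiles -1.34 and -0.84), 14 lower and 0 higher. All 135 tested small RNA genes had a median of 2.38, which goes the other way but holds mostly genes under 200 nt, so this explanation stays open for the histones. A batch of culture, harvest or library that coincides with the groups cannot be told apart from ZsGreen status, since 0 batches named in the labels hold both groups, and a difference in growth state between cultures may be part of it. Faster proliferation of the cells that keep the fluorescence stays open as a hypothesis that these libraries alone do not test.

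More genes were listed at 0 in the ZsGreen-positive libraries, with 606 above 0 in all 3 ZsGreen-negative and at 0 in all 3 ZsGreen-positive libraries and 36 the other way round. Whether fewer fragments were sequenced cannot be decided from the estimated depth, which counts fragments after any scaling. The lower of ZsGreen-positive replicates 2 and 3 had an estimated 12400000 fragments against 9650000 in the deepest ZsGreen-negative library. The tie to replicate 1 allowed only a similar depth in replicates 2 and 3, so this order was fixed by the method. A larger step in these libraries is spoken against by genes at 1 fragment in ZsGreen-positive replicate 1. Of these, 9 and 8 lay at odd whole numbers of the estimated step in replicates 2 and 3, counts that include genes at 1 step, which the tie favours. A small number of distinct molecules amplified to many fragments is a candidate explanation for replicates 2 and 3, in which at most 12.3% of the genes with 1 to 8 fragments were at 1 fragment, against at least 30.2% elsewhere. ZsGreen-positive replicate 1 had 10314 genes at 0 and 30.2% at 1 fragment, so this share does not extend the explanation to it. Its pairs with replicates 2 and 3 differed by 12.84 and 13.85 times the counting variance, so it is not shown to be free of the same fault either. No biological explanation was tested.

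Small RNA genes gave the largest differences between the groups and were left out of the named genes. Of 121 tested genes under 200 nt, 32 were listed at 0 in all ZsGreen-negative and above 10 FPKM in all ZsGreen-positive libraries and 0 the other way round, among them SNORD22 (63432 ± 2276 FPKM in the positive libraries) and SNORA27 (30672 ± 1357 FPKM), chosen after their values were seen. The share of such genes was 26.4% under 200 nt and 0.0167% at 200 to 1000 nt, which is consistent with fragments of another length in the groups, as FPKM of a gene near the fragment length can be inflated or set to 0. All small RNA genes together gave 64 higher and 31 lower of 135 (median 2.38), and whether any of these differed in the cells was not tested.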
